A study of Thermococcus with 6 samples.

How the data were processed

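RNA was sequenced from 6 cultures of a Thermococcus isolate, strain 175, an anaerobic heat-loving archaeon. Per the labels, 3 cultures were grown under 80 to 90 MPa in 60 ml syringes inside titanium vessels and 3 were grown at atmospheric pressure in serum vials. Each culture held 45 ml, was kept at 80 °C in rich medium with sulfur as electron acceptor and was harvested at mid-exponential phase after 10 hours. The groups therefore also differed in culture vessel. Per the labels' protocols, DNA was digested on the column, ribosomal RNA was depleted, and paired-end libraries that keep the strand were made with the dUTP method. Neither the strand setting of the counting nor the genome build is given in the sources used here.

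Bowtie and Cufflinks are named in the submitters' processing notes, without versions. The single table used here has the layout of Cuffdiff, the differential test of the Cufflinks package, per the file headers. It lists 2660 transcripts on 1 sequence called Tc175. For each transcript the authors deposited 1 FPKM value per pressure group, that is, a fragment count scaled for transcript length and library size. The 3 cultures of a group are pooled in that value, so no SD or other error per value can be given, and scaling between libraries is not given in the sources used here. The deposited log2 ratios are high over atmospheric pressure, per the file headers, and differed from ratios recomputed from the FPKM values by at most 1.16e-05. A further deposited column, the test statistic, is a score and was not used. The deposited p-values start at 5e-05, the smallest value listed, which 103 transcripts share. The deposited q-values equal a Benjamini-Hochberg adjustment of those p-values over the 2646 transcripts tested, within 5.14e-07. The other 14 transcripts were marked as not tested. A transcript was called different where the authors' deposited q was under 0.05, which gave the table's own significance mark for all 2660 transcripts.

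The table holds no counts or library totals, so the sequencing depth is unknown and no counting interval is given for an FPKM value. Low FPKM values depend on transcript length and on 3 pooled libraries, and no counts were taken from them. No test across cultures could be made here, and all p-values and q-values of single transcripts are the authors' own. Shares of transcripts called carry exact Clopper-Pearson 95% intervals, which treat transcripts as independent although neighbours often change together.

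The table pairs none of its identifiers with a gene name, and no annotation was used here. The 28 gene lists fixed before the data were examined could therefore not be applied, and transcripts are described by position. Locus starts in the table count from 0, because end minus start is a multiple of 3 for all 1621 transcripts alone in their locus. Starts printed here count from 1. The same multiples show that these gene models hold coding length without untranslated regions. For the 1039 transcripts that share a locus with others, the coordinates are those of the whole locus, of up to 9 transcripts. How far these transcripts overlap is not given. Where they do, their values rest on how reads were divided among them and are less certain.

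A stretch at the start of Tc175 is listed again at its end. It was found after the data were examined, as loci of equal width and with both FPKM values within 0.5% that recur at 1 fixed spacing of 1923946 bases. By position, 419 transcripts were listed 2 times. The main counts follow the table as deposited, and counts with each transcript taken once, at its first listing, stand beside them.

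Before the data were examined, the rule for single features was set. It takes the 12 called transcripts with the largest rise and the 12 with the largest fall among those reaching 10 FPKM in either group, the 5 with the highest mean FPKM, and the 3 longest runs of 3 or more adjacent transcripts called in the same direction. At most 2 identifiers are printed per direction, and up to 3 transcripts listed at 0 in 1 group are named without a fold. The rule was applied with each transcript counted once. Folds are ratios of the authors' deposited group FPKM. The number of runs was set against 1000 shuffles of the calls among tested transcripts.

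Alternatives were a q threshold of 0.01, a minimum of 2-fold, a Bonferroni correction, recomputed adjustment, a mean of at least 10 FPKM, recentring, rescaling to TPM, pseudocounts of 1 and 10 FPKM, and leaving out transcripts in shared loci or in loci under 200 bases. Counting each repeated transcript once, at either listing, leaving those transcripts out and removing a trend along the sequence were added after seeing the data. So were TPM for the median log2 ratio, also with each transcript counted once, and for single transcripts. Added then too were the q threshold of 0.01 for the share called by level, the minimum of 10 FPKM for the median log2 ratio, and doubling the FPKM of the repeated transcripts. The trend around the whole listed length, without the repeated transcripts, and without the 9 of 90 blocks that add most to it was also added then. Those blocks were taken out in turn, each time the block whose loss lowers the amplitude most. The trend was a single sine wave around a circle of 1923946 bases, tested with 10000 shuffles of blocks of 25 neighbouring transcripts and 2000 block bootstrap resamples.

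The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The adjustment was tested on simulated data with 2646 transcripts, of which 200 were shifted by a large known amount, and it recovered 98.0% of those with 2.49% false calls. The simulated p-values were independent, without the floor of the deposited ones and without transcripts listed in duplicate. These rates check the calculation and say nothing of the deposited calls. The trend test, on simulated data with 2200 transcripts, called 6% of data sets without a trend and 100% of those with a planted one. In those data neighbours were alike only over stretches shorter than the shuffled blocks. False calls under longer clustering were therefore not examined.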

Results

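Transcript levels of Thermococcus strain 175, a sulfur-reducing archaeon from a deep hydrothermal vent, were compared between 3 cultures grown at 80 to 90 MPa and 3 grown at atmospheric pressure, to find which transcripts differ when the cells grow under pressure. All cultures grew at 80 °C. The authors' deposited table gave 1 FPKM value per transcript and group for 2660 transcripts at 2059 loci of the sequence Tc175. There was no value per culture, so the values below carry no error of their own and the test of each difference is the authors'. The median FPKM of the 2646 tested transcripts was 158 at atmospheric pressure and 171 at high pressure. The central 90% of tested transcripts lay between 48.4 and 1604 FPKM at atmospheric pressure and between 43.7 and 1299.7 FPKM at high pressure.

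At high pressure 116 transcripts rose and 172 fell, by the authors' deposited table at q under 0.05. These were 10.9% of the transcripts tested. The transcripts that rose had a median of 144 FPKM at atmospheric and 390 FPKM at high pressure, and a median rise of 2.53-fold. Those that fell had medians of 584 and 232 FPKM, and a median fall of 2.40-fold. At least a 2-fold difference was reached by 97 of the transcripts that rose and 134 of those that fell. The largest rise was 10.5-fold and the largest fall 28.9-fold. The median log2 ratio over all tested transcripts was 0.01, with quartiles of -0.44 and 0.41.

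Part of the sequence was listed in duplicate. The loci from base 424 to base 370381 recurred from base 1924370 to base 2294327, the last base listed, with 419 transcripts in each listing. Both FPKM values of a transcript agreed within 1% between its listings for 368 of the 419 pairs. This stretch held 11 rises and 45 falls at its first listing and 11 rises and 43 falls at its second, by the authors' deposited table. Outside it, 94 of 1810 tested transcripts rose and 84 fell. With each transcript counted once, 105 of 2228 tested transcripts rose and 129 fell at the deposited q. With the adjustment recomputed over these 2228, 105 rose and 126 fell. The rises thus made up 40.3% of the calls as deposited and 45.5% when each transcript was counted once with q recomputed. All values that follow count each transcript once, except where stated.

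**Figure D1:**
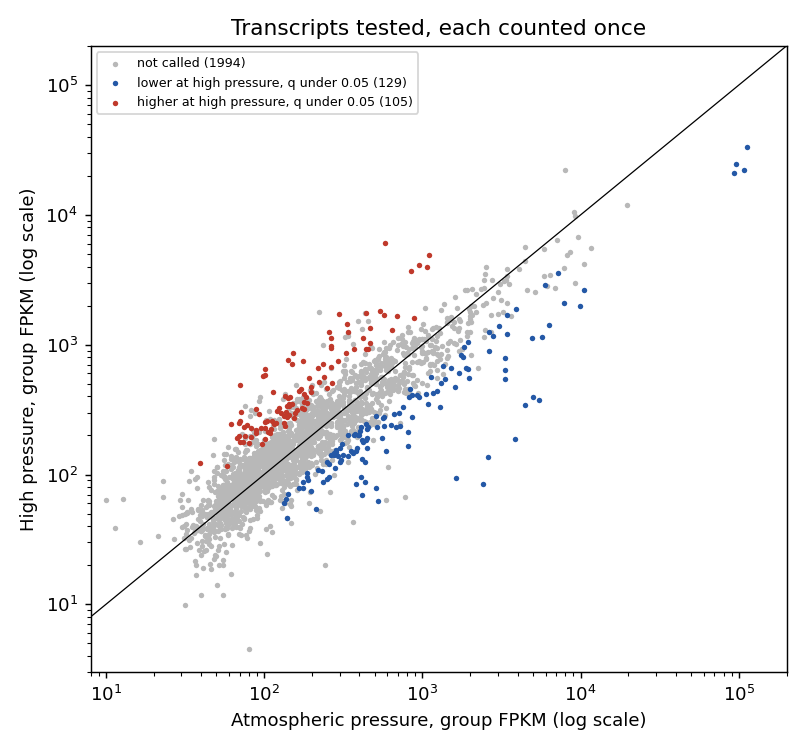
Group FPKM at high pressure against group FPKM at atmospheric pressure, both on log scales, for the 2228 tested transcripts counted once. Each point is a transcript, the line marks equal values, and red and blue points are the 105 higher and 129 lower transcripts at a deposited q under 0.05. The 4 blue points at the far right are the abundant transcripts that fell from 92777 FPKM or more.

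Of the 5 transcripts with the highest mean FPKM, 4 fell at high pressure. A transcript of a 1263-base coding locus at bases 1868001 to 1869263 fell from 113299 to 33377 FPKM, or 3.39-fold. A 1242-base locus at bases 338826 to 340067 fell 4.83-fold, from 107271 to 22216 FPKM. A short 177-base locus at bases 283077 to 283253 fell 3.89-fold, from 96140 to 24745 FPKM. A 1221-base locus at bases 311835 to 313055 fell 4.38-fold, from 92777 to 21175 FPKM. In the authors' deposited table the q values of these 4 transcripts, in the same order, were 0.0320, 0.0348, 0.00128 and 0.00966. The remaining transcript of the 5 with the highest mean FPKM, at bases 190982 to 192790, had 19545 FPKM at atmospheric and 11945 FPKM at high pressure and was not called, with a q of 0.522 in the authors' deposited table. All of these except the transcript at base 1868001 lie in the stretch listed in duplicate. Together the 5 transcripts made up 31.3% of the summed FPKM at atmospheric pressure and 11.98% at high pressure, with each transcript counted once. Whether the authors' processing divided reads between the listings is not given in the sources used here. If it did, the FPKM of transcripts in that stretch would be too low by up to 2-fold, and doubling them gives shares of 40.0% and 16.7%, with the same 5 transcripts at the top. Scaling both groups to the same sum would raise every log2 ratio alike, by 0.53 with each transcript counted once and by 0.68 over all listings. The smallest called fall, 1.70-fold, exceeds the larger of these shifts, which is 1.602-fold, so no called fall would become a rise. Every fall would shrink by the shift, however, and the authors' test could not be rerun under such scaling. How many rises and falls would then be called is unknown.

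The longest run of neighbouring transcripts that rose together lay at bases 909994 to 916676 and held 8 transcripts. Their rises ranged from 3.70-fold to 6.45-fold, and the largest q among them in the authors' deposited table was 0.00797. The 4 transcripts at its high-numbered end, from base 913378, were the more abundant ones, at 847 to 1095 FPKM at atmospheric pressure and 3707 to 4920 FPKM at high pressure. Just beyond them, the transcript at bases 916731 to 917387 had 7985 and 21980 FPKM, but was not called, with a q of 0.227 in the authors' deposited table. On the other side, 1 of the 2 transcripts sharing the locus at bases 906319 to 909980 rose 6.98-fold, from 70.2 to 490.1 FPKM, and carries the identifier 2545870385. The other transcript of that locus had 81.3 and 283.1 FPKM and was not called. The transcript next to that locus, at base 905607, rose from 69.0 to 248.4 FPKM.

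A second run of 6 transcripts that rose lay at bases 1237986 to 1245510, with rises of 2.03-fold to 3.03-fold and a largest q of 0.0255 in the authors' deposited table. Levels there reached 1350 FPKM at high pressure, against 468 FPKM at atmospheric pressure, at base 1242356. The other transcript of the run's first locus, at base 1237986, had 115 and 140 FPKM and was not called. The run was followed by a transcript at base 1245516 that had 160 and 380 FPKM but was not called. After it 2 more rose, at bases 1245516 and 1246933, from 327 to 856 FPKM and from 295 to 752 FPKM.

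The largest rise of all was in a neighbourhood of the duplicated stretch. The transcript with the identifier 2545869619, 1 of 2 in the locus at bases 301606 to 303674, rose 10.5-fold, from 578 to 6051 FPKM, with a q of 0.00128 in the authors' deposited table. The transcript at bases 301012 to 301473 next to it rose 5.8-fold, and both transcripts of the locus at bases 303685 to 305660 rose, by 5.81-fold and 4.88-fold. The other transcript of the first locus had 224 and 1781 FPKM and was not called, with a q of 0.608. The transcript at bases 300719 to 301003 fell in the same neighbourhood, from 1230 to 441 FPKM. Of the remaining largest rises, the transcript at bases 1270666 to 1272126 rose 5.67-fold and 1 of 4 transcripts of the locus at bases 973095 to 976465 rose 4.70-fold.

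The longest run that fell lay at bases 872027 to 876010. Its first 4 transcripts fell from 5435, 4447, 5009 and 1639 FPKM to 378, 341, 394 and 94.4 FPKM, which is 12.7-fold to 17.4-fold. The last, a 240-base locus at base 875771, fell 2.29-fold. The largest q in this run was 0.0174 in the authors' deposited table. The 3 transcripts on its low-numbered side, from base 870534, had between 103 and 152 FPKM at atmospheric pressure and between 108 and 128 FPKM at high pressure, and were not called.

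**Figure D2:**
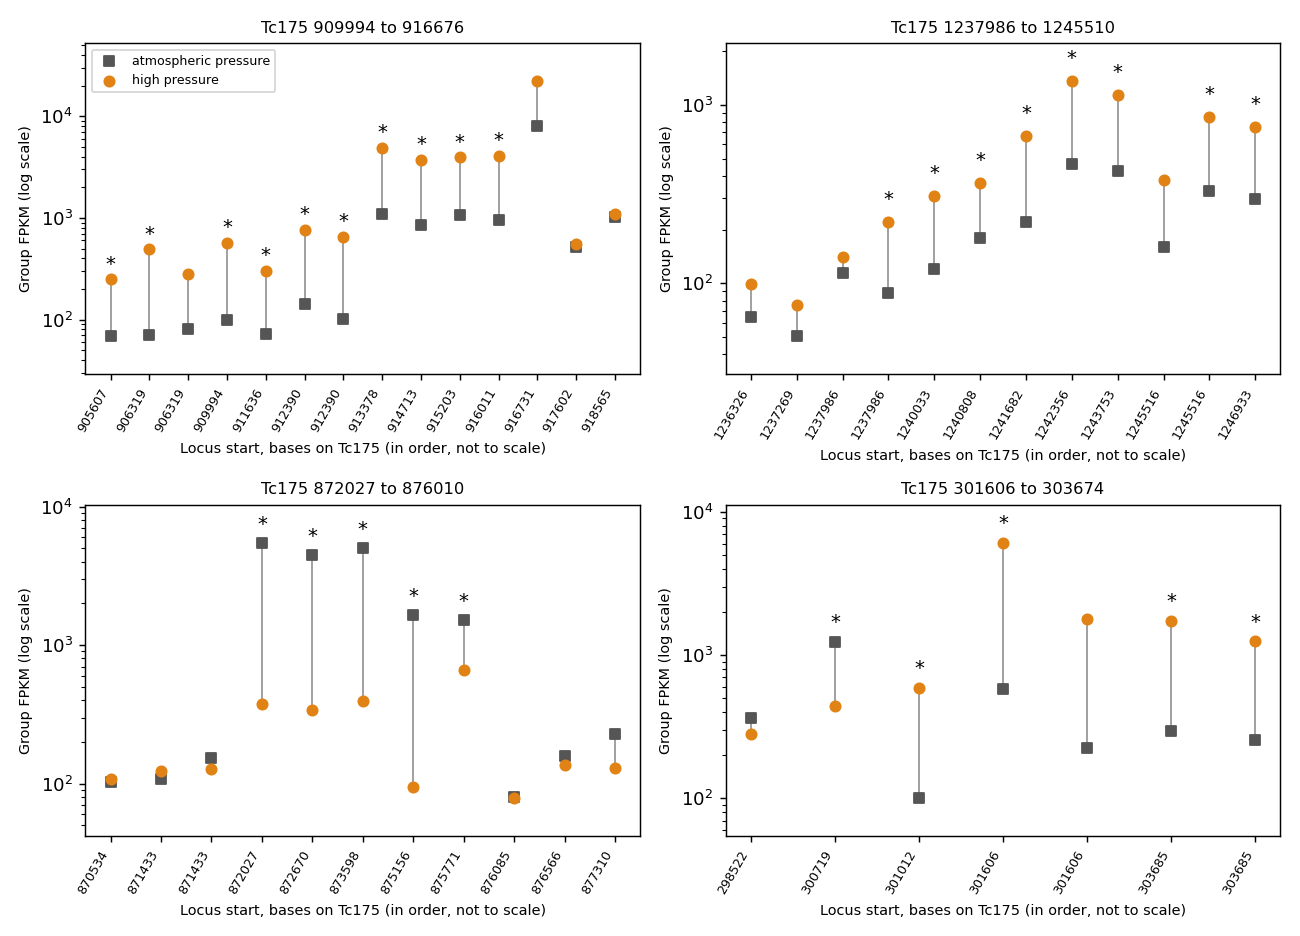
Group FPKM on a log scale at atmospheric pressure (squares) and high pressure (circles) for the 3 longest runs and for the largest rise, with 3 neighbouring transcripts on each side, in sequence order and not to scale. Stars mark a deposited q under 0.05. The run at base 872027 falls from between 1514 and 5435 FPKM to between 94.4 and 660 FPKM, and the 6 transcripts shown around it carry no star.

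The 3 largest falls were in transcripts that stood alone in their locus. The transcript with the identifier 2545869960, at bases 584536 to 584985, fell 28.9-fold, from 2429 to 84.1 FPKM. The transcript with the identifier 2545870258, a 249-base locus at bases 808011 to 808259, fell 20.5-fold, from 3840 to 187 FPKM. A 1704-base locus at bases 1016082 to 1017785 fell 19.2-fold, from 2606 to 136 FPKM. All 3 had a q of 0.00128 in the authors' deposited table, the smallest it holds. Further falls among the 12 largest were in loci at bases 525364 to 526194 (8.37-fold), 1740472 to 1740762 (6.49-fold), 325522 to 325743 (6.19-fold) and 950033 to 950341 (5.14-fold), and in 1 of the 2 transcripts at bases 521783 to 522720 (5.94-fold). Among these 12 falls, 11 were in transcripts alone in their locus, against 5 of the 12 largest rises and 1359 of the 2228 tested transcripts. Most of those rises lay at bases 301012 to 305660 and 906319 to 915189, and several of the falls in the run at base 872027. The 12 of each direction are therefore not independent.

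Calls came in runs along the sequence. There were 13 runs of 3 or more adjacent transcripts called in the same direction, 8 of rises and 5 of falls, which held 52 of the 234 calls. Shuffling the calls among tested transcripts 1000 times gave 0.574 such runs on average and at most 3. The shuffles kept neither the level of a transcript nor its place in a shared locus. Transcripts of the same locus count as neighbours, as with 2 of the 8 in the longest run, at bases 912390 to 913345. Rises and falls were also unevenly spread. Between bases 900001 and 1700000, 76 of 900 tested transcripts rose and 26 fell by the authors' deposited table, while 29 of 1328 rose and 103 fell elsewhere. The median log2 ratio was 0.28 inside this part and -0.13 outside it. The limits of this part were chosen after its values were seen.

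**Figure D3:**
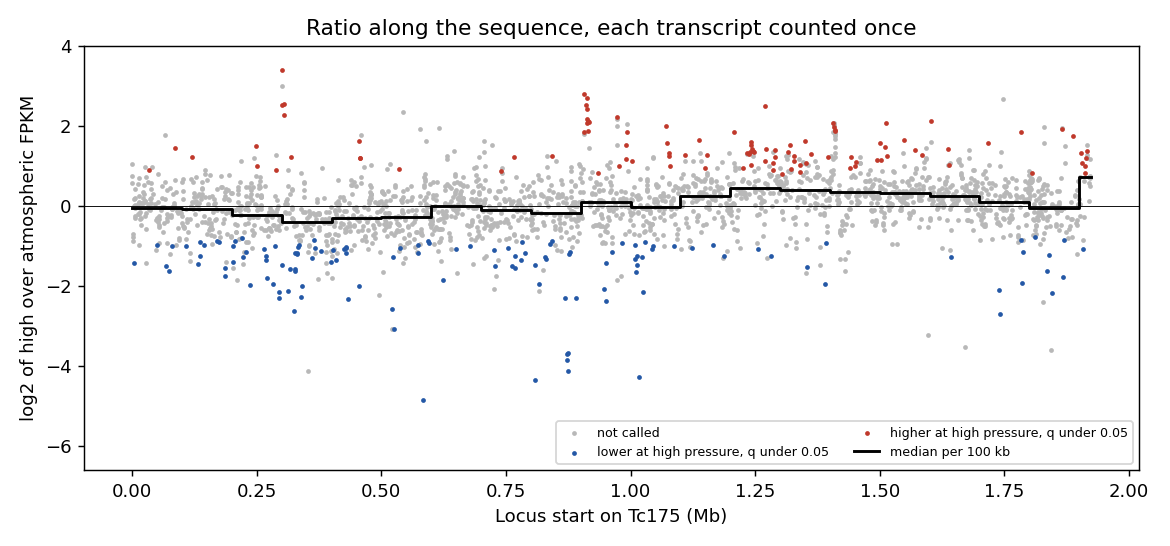
The log2 ratio of high over atmospheric pressure FPKM against locus start on Tc175 in megabases, for tested transcripts counted once. Points are transcripts, coloured by their call, and the black line is the median per 100000 bases. The line lies above 0 in every window from base 1100001 to base 1800000, where it reaches 0.44, and is lowest, at -0.40, from base 300001 to base 400000. The last window holds 25 transcripts and has a median of 0.72.

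The share of transcripts called by the authors' deposited table was larger at higher levels. In the quintile of tested transcripts with the lowest mean FPKM, 20.7 to 81.2, there was 1 rise and 0 falls among 457, or 0.219% (exact 95% interval 0.00554% to 1.21%). In the middle quintile, 34 rose and 21 fell among 446, or 12.3% (9.43% to 15.7%). In the highest quintile, above 456.7 FPKM, 30 transcripts rose and 60 fell among 440, or 20.5% (16.8% to 24.5%). With every listing counted, the lowest quintile held 0.189% called and the highest 21.5%. Among transcripts with at least a 2-fold difference, 1 of 43 was called in the lowest quintile and 83 of 114 in the highest.

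Transcripts listed at 0 were not tested. As deposited, 2 transcripts were listed at 0 at atmospheric pressure only, 3 at high pressure only and 3 in both groups. The 2 at atmospheric pressure were the listings of 1 transcript, a 93-base locus at bases 236127 to 236219, with 221 FPKM at high pressure. At high pressure a transcript in the locus at bases 619419 to 619687 was listed at 0, against 134 FPKM at atmospheric pressure, and 1 in the locus at bases 1711868 to 1712193 was listed at 0, against 53.9 FPKM. No fold is given for these.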

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

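Chosen only after the data were seen were the tests that treat transcripts listed in duplicate or the trend along the sequence, the stricter threshold for the share called by level, and the 10 FPKM minimum and TPM for the median log2 ratio, with TPM for single transcripts. Counts here are over all listings except where stated. Under a q threshold of 0.01 the 116 rises became 75 and the 172 falls 103, and the share called in the highest quintile of FPKM went from 21.5% to 14.9%. A Bonferroni correction left 0 rises and 0 falls by construction, because the smallest p-value the authors' deposited table holds, 5e-05, times 2646 tests is above 0.05. At an unadjusted p under 0.05 that table held 537 transcripts. Leaving out the transcripts listed in duplicate, with the adjustment recomputed, gave 94 rises and 83 falls, so rises then outnumbered falls. Rescaling to TPM moved the median log2 ratio from 0.01 to 0.69, or to 0.59 with each transcript counted once. Counts stayed within 1.5 times of the main ones with at least 2-fold differences, without shared or short loci and with the adjustment recomputed over the rest (95 rises and 167 falls), and with either listing counted once, also recomputed. Several alternatives could not move the counts and say nothing of their stability. The recomputed adjustment equals the deposited one, the minimum of 10 FPKM removed no tested transcript, and recentring, TPM and removal of the position trend keep the deposited q, so only a direction could have changed. For the 39 transcripts of the naming rule, pseudocounts cannot turn a direction, and a pseudocount of 10 FPKM moved log2 ratios by at most 0.19. Under TPM the transcript at base 190982, which was not called, came closest to 0, going from -0.71 to -0.03. No paired analysis was possible because the table holds 1 pooled value per group. For the same reason no replicate could be left out, and no other split of the cultures could be made, so neither the weight of a single culture nor a chance division of the cultures was examined. The gene list comparisons planned beforehand were not run, since the table pairs no identifier with a gene name.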

Other observations

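The test of lower expression in shared loci was set before its result was seen, and the other tests in this part were chosen after the data were seen. Beyond the 3 longest runs, neighbouring transcripts moved together in 10 more places. Among rises, 4 transcripts at bases 1911954 to 1916810 rose 1.76-fold to 2.59-fold, and 3 at bases 1511337 to 1514601 rose 2.38-fold to 4.23-fold. Runs of 3 rises also lay at bases 455833 to 458446, 991057 to 995631, 1270077 to 1273298 and 1286731 to 1290678, with median rises of 2.31-fold, 2.86-fold, 2.67-fold and 2.34-fold. Among falls, 4 transcripts at bases 325522 to 327966 fell 2.25-fold to 6.19-fold, and 4 more at bases 330934 to 334963 fell 1.96-fold to 2.28-fold. Runs of 3 falls lay at bases 267792 to 272673, with a median fall of 2.53-fold, and at bases 1011348 to 1013977, with a median fall of 2.76-fold. In the runs from base 267792 and from base 991057, more than 1 transcript comes from the same locus, and every transcript shares its locus with others. Calls are those of the authors' deposited table.

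For the listing of 1 stretch at both ends of Tc175, the possible explanations are overlapping ends of a circular sequence left untrimmed, and a second copy of the segment present in the cells. The first locus, bases 2 to 397, ends 0 bases from where the locus at bases 1922778 to 1924343 ends once the spacing of 1923946 bases is subtracted, as though it were the cut end of that locus. Untrimmed ends would give this, but a sequence that begins inside a true second copy would give it too. Untrimmed ends were also expected to cut the last listed locus, and it is not cut: it ends at base 2294327, which less the spacing is base 370381, where its partner ends. A sequence that ends between loci would leave the last locus whole, so this excludes neither. The partners' log2 ratios differed by 0.00268 in the median and by 0.415 at most, and 2 of the 419 pairs were called at 1 listing only. Reads of identical copies cannot be assigned, however. The explanations cannot be told apart from this table.

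The log2 ratio followed position along the sequence. A single wave around a circle of 1923946 bases, a length that takes the repeated stretch as overlap, had an amplitude of 0.33 on the log2 scale (95% block bootstrap interval 0.27 to 0.41), peaked near base 1402519 and explained 8.76% of the variance across 2228 transcripts. The amplitude was 0.32 (0.25 to 0.38) around the whole listed length of 2294327 bases with every listing kept, and 0.33 (0.25 to 0.41) without the transcripts listed in duplicate, so it does not rest on that length. Clustering of neighbours alone, over stretches shorter than the shuffled blocks, is argued against. Shuffled blocks of 25 transcripts fitted as well with a permutation p of 0.0001, the smallest that 10000 shuffles can give. Blocks of 50 and of 100 transcripts gave the same permutation p. A few strongly changed regions do not account for it either. Without the 9 of 90 blocks that add most to the wave, the amplitude was 0.26 (0.20 to 0.32) with a permutation p of 0.0001. The fit without called transcripts, with an amplitude of 0.25, excludes nothing, because many transcripts that differ by 2-fold or more are not called and stay in it. Genomic DNA carried into the libraries would add to every transcript, weak ones included. A background at the 5th percentile of tested transcripts, 48.0 FPKM, would allow an amplitude of 0.0721 in the highest quintile of FPKM. That bound takes the background to lie in 1 group only and every transcript at or above 456.7 FPKM, the lowest mean there. The quintile had 0.52 (0.32 to 0.74). A background at the lowest tested mean, 20.7 FPKM, would allow less. Transcripts of the quintile that are weak in 1 group, or opposite backgrounds in both groups, would allow more. How much more was not computed. Within those assumptions the quintile argues against carried DNA as the only source of the wave. Carried DNA was also expected to give a larger amplitude in the 1114 transcripts with the lower mean FPKM. They had 0.33, against 0.36 in the 1114 with the higher mean. The difference of -0.02 (95% block bootstrap interval -0.15 to 0.09) leaves open that carried DNA adds to the wave among weaker transcripts. Also open are a difference between the groups in gene copy number along the replicating chromosome, and an uneven placement of pressure-responsive genes. The copy number difference may follow growth rate. Neither these nor the difference in culture vessel was tested. The shuffles and resamples above moved transcripts, with 1 pooled value per group. They measure spread along the sequence and not between cultures, so whether each culture holds the wave is unknown.

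Transcripts that share a locus were called less often, at 4.72% of 869 (exact interval 3.41% to 6.35%) against 14.2% of 1359 alone in their locus (12.4% to 16.2%). Lower expression of transcripts in shared loci leaves the gap in place, since standardising them to the levels of the single ones gave 5.73%. Among transcripts with at least a 2-fold difference and a mean of at least 100 FPKM, 35.8% of 109 in shared loci were called (26.8% to 45.5%), against 77.1% of 192 alone (70.5% to 82.8%). A candidate explanation is that dividing reads among overlapping transcripts widened the authors' error estimates, though how far they overlap is not given. No biological explanation was tested. In the authors' deposited table, single transcripts of the shared loci at bases 1844026, 1670817 and 521783 had a 12.1-fold, 11.5-fold and 8.47-fold lower level at high pressure. Their q values were 0.843, 0.677 and 0.667. These are examples with large folds, and the first had only 20.1 FPKM at high pressure. An uncalled transcript in a shared locus may thus still differ by much, but such a fold may also be noise.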
